A study of Mus musculus with 4 samples.

How the data were processed

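Gene expression was measured in whole dorsal skin of male C57B6 mice on 4 arrays, 2 from postnatal day 54 (P54) and 2 from postnatal day 59 (P59), both in adult telogen, the resting phase of the hair cycle. Per the labels' protocols, the shaved skin was excised after death into an RNA-preserving solution, RNA was extracted with Trizol and purified on columns, and biotin-labelled cRNA was made from total RNA by the standard Affymetrix procedure. The labels call the samples biological replicates but do not say which animals they came from, or how many animals made up a sample. The p-values of single genes therefore measure the spread between these samples. The hour of day at which skin was taken is not given in the sources used here.

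The authors deposited 1 table of probe set intensity values on a linear scale for all 4 arrays. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays to a common distribution and summarises the probes of each set, and Affymetrix Expression Console, with no version given in the sources used here. The deposited intensity values ran from 6.41 to 24000, with medians of 66.9 and 69.3 in P54 replicates 1 and 2 and 67.2 and 64.7 in P59 replicates 1 and 2. The values were taken to log2 without a pseudocount. Differences between groups are therefore differences of mean log2 intensity, and the number of arrays, 2 per group, limits their precision.

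The table held 45101 probe sets, of which 64 were control sets of the array maker. GEO's platform annotation, which can be old, listed 34958 probe sets with 1 gene symbol and 932 with several, and left 9211 unlisted. Sets with several symbols or none were left out of the gene tests, and 34754 of those with 1 gene matched a gene of the RefSeq annotation of GRCm38.p6 by Entrez identifier, with 0 symbols renamed. That annotation was used for names alone, since no genome build is named with the values, and no coordinates are given. Where a gene had several probe sets, as 9010 of 18193 genes did, the set with the highest mean over the 4 arrays was used. Genes above the 40th percentile of mean log2 intensity (6.58, an intensity of 95.5) were tested, which left 10916 genes.

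P59 was compared with P54 in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without an intensity trend, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fit has 2 residual degrees of freedom per gene, to which the shared prior adds 8.18. No exact permutation test of 2 arrays against 2 can reach 0.05, since the 4 arrays can be split in only 3 ways, and the adjusted p-values are those of limma's moderated test. A second count, of genes at an unadjusted p under 0.05 and at least 1.5-fold apart, describes the data and controls no false discovery rate. Of 50 gene lists for pathways and for cell types of dorsal skin, the 47 with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. With an estimated correlation camera draws on the 2 residual degrees of freedom, so a list could hardly pass it whatever its correlation. With the preset correlation it compares the members of a list with the other genes. Those p-values rest mainly on the spread over genes, and do not measure the spread between samples.

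The genes named are, by a fixed rule, the 10 with the largest difference in each direction and up to 4 members of each list described, those with the smallest p. The 10 were taken first from genes past the adjusted threshold and then, where these ran out, from genes at an unadjusted p under 0.05, in both cases with groups that did not overlap. Symbols of clones and Y-linked genes were passed over in that ranking. Telogen regulators, clock genes and a check of sex were always named, and other genes are said to have been chosen after their values were seen. The groups, the tests, the lists, the naming rule and the alternatives were chosen before the data were examined.

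The procedure was tested on simulated data, in 20 runs of 10916 genes with 200 changed genes each, for P59 against P54. At the adjusted threshold 20.5% of 2-fold and 97% of 4-fold changes were recovered, with a mean of 6.1 unchanged genes called per run. At the unadjusted p with the fold limit the shares were 91.0% and 99.95%, with 394.4 unchanged genes per run. A simulated shift of 0.5 (log2) in the macrophage list was called in 20 of 20 runs, with 0.25 unshifted lists called per run when genes varied independently. The simulated arrays were of equal quality and all their genes varied independently, whereas P59 replicate 2 stood apart in the data. These rates may therefore not hold for the data, where another split of the 4 arrays called 14 lists.

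The alternatives changed 1 choice at a time: no intensity filter, a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, a prior with an intensity trend and robust estimation, a repeated quantile normalization, centring of each array on its median, array weights, the replicate number as a block, and leaving out each array in turn. As a measure of RNA quality, the log2 gap between the 3' and the 5' control probe set was taken for 4 mouse transcripts on each array. Figures were drawn with matplotlib 3.10.9.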

Results

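Dorsal skin of male C57B6 mice was profiled at 2 times of adult telogen, a middle time (P54) and a late one (P59), with 2 arrays per time. After filtering, 10916 genes were compared to ask which transcripts differ between middle and late telogen. Median log2 intensity was 6.06 and 6.12 in P54 replicates 1 and 2 and 6.07 and 6.02 in P59 replicates 1 and 2. The P54 arrays resembled each other most, with a Spearman correlation of 0.976 across genes. The P59 arrays reached 0.930 with each other and P59 replicate 1 reached 0.970 with P54 replicate 1. P59 replicate 2 stood apart on the first principal component, which held 57.3% of the variance. It had a score of 35.4 against -8.57, -22.5 and -4.31 for P54 replicates 1 and 2 and P59 replicate 1. The male label was checked with sex-linked transcripts: Xist lay between 5.51 and 5.87 on the 4 arrays, below the intensity filter, while the Y-linked Eif2s3y lay between 9.28 and 9.82, Uty between 6.95 and 7.89 and Kdm5d between 7.33 and 7.98. Ddx3y had no probe set listed with it alone.

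The P59 arrays held more transcript of S100a8 and Akr1cl than the P54 arrays, and structural genes of the growing hair follicle were among the genes with the largest differences. The calls of S100a8 and Akr1cl past the adjusted threshold were lost in several alternatives, such as testing without the intensity filter. S100a8, a calcium-binding protein abundant in neutrophils and in stressed keratinocytes, rose 4.50-fold, from a mean log2 intensity of 6.35 ± 0.01 to 8.52 ± 0.35 (SD, n = 2 per group). Akr1cl, a member of the aldo-keto reductase family, rose 4.65-fold, from 5.50 ± 0.19 to 7.71 ± 0.42. The inner root sheath genes Krt25, Tchh and Krt71 were higher at P59 on average, but their replicates lay far apart. Their P54 means of 5.85, 6.38 and 6.26, like those of S100a8 and Akr1cl, were below the intensity filter of 6.58, so the folds given for these 5 genes are rough. Macrophage and complement genes were mostly higher at P59, and genes of adipocytes and of the epidermis were mostly lower, by smaller amounts. None of these lists passed with an estimated correlation (adjusted p = 0.600 to 0.700).

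In limma's fit the log2 difference of S100a8 was 2.17 (95% interval 1.62 to 2.72) and that of Akr1cl 2.22 (1.63 to 2.81), both with an adjusted p of 0.0387 and both higher in 2 of 2 P59 arrays than in either P54 array. The probe set of S100a8 is of a kind that can match more than 1 transcript, and the 2 group means lie on either side of the intensity filter for both genes. These were the 2 genes of 10916 past the adjusted threshold, and 0 genes were lower past it. In the same limma fit 708 genes had an unadjusted p under 0.05 where chance alone would give 545.8. At an unadjusted p under 0.05 and a 1.5-fold difference there were 607 genes, 331 higher and 276 lower at P59. In the simulated runs a mean of 394.4 unchanged genes met these limits. The difference was larger in P59 replicate 2 than in P59 replicate 1 for 69.2% of the higher and 77.9% of the lower genes. The groups did not overlap for 33.7% of genes tested, against 33.3% by chance. Testing all genes without the filter, applying a stricter filter, averaging probe sets, testing each probe set or normalizing again left 0 genes past the adjusted threshold in limma, with 457 to 1501 at an unadjusted p under 0.05. Leaving out 1 array at a time, the log2 difference ranged from 1.92 to 2.42 for S100a8 and from 1.92 to 2.52 for Akr1cl.

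**Figure D1:**
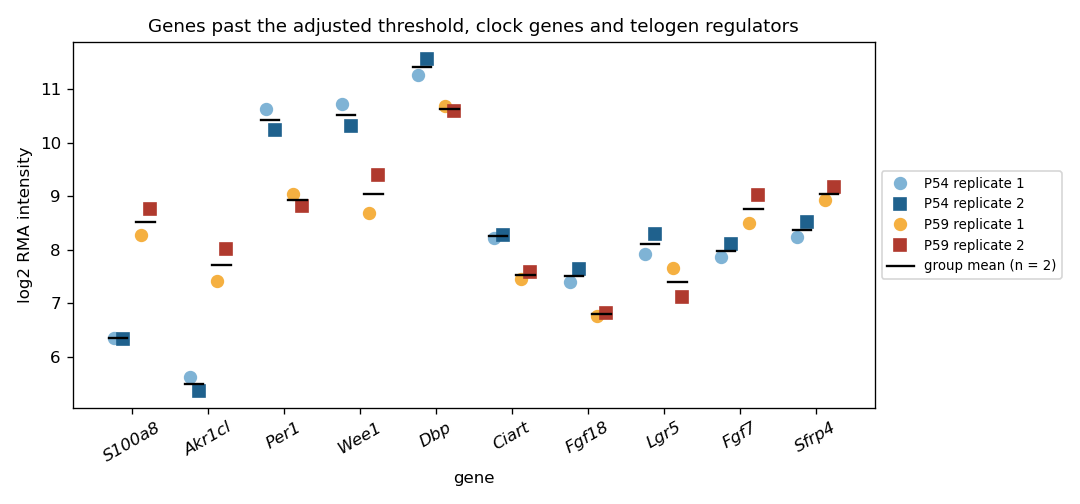
Log2 RMA intensity (vertical axis) of the 2 genes past the adjusted threshold, 4 genes of the clock list and 4 telogen regulators (horizontal axis) on each array, with circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). S100a8 lay at 6.36 and 6.34 at P54 and at 8.28 and 8.77 at P59. The groups of all 10 genes drawn are separate, as are those of 33.7% of all genes tested. Bmp2, Bmp4, Axin2, Cd34, Per2 and Nr1d1, named in the text with groups that overlap, are not drawn.

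The other 8 of the 10 genes with the largest positive differences were not past the adjusted threshold. Sln, the sarcolipin gene of muscle, was 6.19-fold higher at P59 (log2 difference 2.63, SE 0.41, adjusted p = 0.0934), and the mean of its probe sets differed by 1.38. Krt25 was 22.9-fold higher (4.51, SE 0.85, adjusted p = 0.179), with log2 intensities of 7.21 and 4.49 at P54 and 11.64 and 9.09 at P59. Tchh, which encodes the inner root sheath protein trichohyalin, was 15.1-fold higher (3.92, SE 0.68, adjusted p = 0.141). Krtap8-1, a keratin-associated protein gene of the hair shaft, differed by 3.92 (adjusted p = 0.179), Krt71 by 3.75 (adjusted p = 0.248), Krt27 by 3.70 (adjusted p = 0.179), Prr9 by 3.08 (adjusted p = 0.179) and Krt28 by 2.64 (adjusted p = 0.370). Of these 8 genes Sln and Prr9 alone had a P54 mean above the intensity filter. Without P59 replicate 1 all 8 differed by less: Krt25 by 3.24, Tchh by 2.82, Krt27 by 2.80 and Krtap8-1 by 2.71. Krt71 then differed by 2.15, Sln by 1.97, Prr9 by 1.86 and Krt28 by 1.36. Among genes chosen after their values were seen, Ctxn3 (2.04), Aldh1a3 (1.71), a retinoic acid synthesis enzyme, and Pla1a (1.63), a phospholipase, each had an adjusted p of 0.0668. Their P54 means of 6.51, 5.84 and 6.17 were below the intensity filter, so these differences are rough too. Other probe sets of Aldh1a3 differed by 0.93 and 0.50.

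The inner root sheath list, fixed for the sheath that surrounds the growing hair, had a median log2 difference of 2.32, or 4.98-fold, with 8 of its 10 tested members higher and 2 lower. Its adjusted p was 1.68e-06 with the preset correlation, and adjusted p = 0.600 with an estimated correlation. In limma's fit 6 members passed adjusted over the list alone, and 0 over all genes tested. The hair shaft list had a median of 0.85 with 10 of 11 members higher, an adjusted p of 5.01e-06 with the preset correlation, and adjusted p = 0.617 with an estimated correlation. Of its members 3 passed adjusted over the list alone, and 0 over all genes tested. Beside Krtap8-1, the shaft keratin genes Krt31 (1.71, adjusted p = 0.498), Krt81 (1.48, adjusted p = 0.478) and Krt33b (1.48, adjusted p = 0.608) were higher. P59 replicate 1 held the highest level of each of the 10 follicle genes plotted: Krt31 was at 8.59 there, at 6.53 in P59 replicate 2, and at 6.13 and 5.56 at P54. Without P59 replicate 1 Krt31, Krt81 and Krt33b differed by 0.68, 0.71 and 0.39. The median of the inner root sheath list was then 1.03 (adjusted p = 0.0811) and that of the shaft list 0.32 (adjusted p = 0.172).

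**Figure D2:**
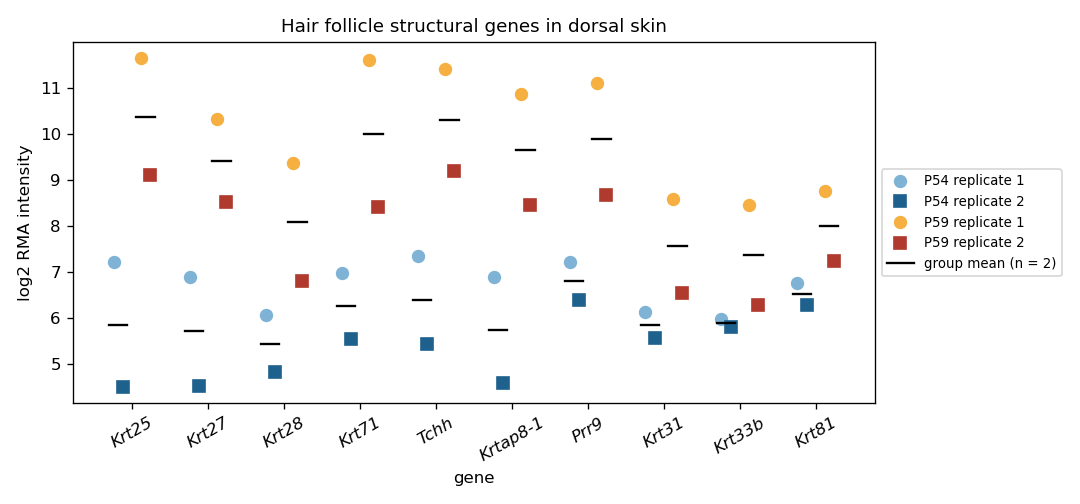
Log2 RMA intensity (vertical axis) of 10 hair follicle structural genes (horizontal axis) on each array, with circles for replicate 1, squares for replicate 2 and bars for group means (n = 2). P59 replicate 1 is the highest array for each gene, with Krt25 at 11.64 against 9.09 in P59 replicate 2, and the P54 arrays are lowest, at 7.21 and 4.49 for Krt25.

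The macrophage list was higher at P59, with 21 of 22 tested members up, a median log2 difference of 0.45 and an adjusted p of 4.35e-06 with the preset correlation. It was not past the threshold (adjusted p = 0.600) with an estimated correlation. Of these members 2 passed adjusted over the list alone, and 0 over all genes tested. The median of the macrophage list was 0.32 without P54 replicate 2 and 0.59 without P54 replicate 1. Mpeg1, which encodes a pore-forming protein of macrophages, was higher by 0.96 (SE 0.25, adjusted p = 0.402), Ms4a7 by 0.93 (adjusted p = 0.337), the Fc receptor gene Fcgr3 by 0.70 (adjusted p = 0.599) and Cd68 by 0.65 (adjusted p = 0.624). The complement list had a median of 0.47, with 12 of 13 members higher and an adjusted p of 1.04e-06 with the preset correlation. It was not past the threshold (adjusted p = 0.600) with an estimated correlation. The count adjusted over the list alone was 5, and it was 0 over all genes tested. The terminal pathway component C6 was higher by 1.79 (SE 0.27, adjusted p = 0.0934), the receptor genes C5ar1 by 1.43 (adjusted p = 0.179) and C3ar1 by 1.10 (adjusted p = 0.234), and the lectin pathway protease gene Masp1 by 1.02 (adjusted p = 0.478). A second probe set of C5ar1 differed by 0.20 and the mean of its sets by 0.81, and Masp1 differed by 0.63 without P59 replicate 2. Of the C1q genes, which stand on both lists, C1qb differed by 0.28 and C1qc by 0.23 (-0.22 and -0.02 without P59 replicate 1), and the mean of the C1qb sets by 0.53. C1qa was the tested member of both lists that was lower (-1.18), at 9.76 and 10.09 at P54, 10.40 in P59 replicate 1 and 7.09 in P59 replicate 2. Without P59 replicate 1 the complement list had a median of 0.50 and an adjusted p of 0.0770, and without P54 replicate 2 its median was 0.33.

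The interferon response list had a median of 0.26, with 23 of 26 members higher and an adjusted p of 0.00123 with the preset correlation. It was not past the threshold (adjusted p = 0.700) with an estimated correlation. Its difference lay in P59 replicate 1: the guanylate-binding protein gene Gbp2 was at 10.98 there, at 9.12 in P59 replicate 2, and at 8.99 and 8.70 at P54. Irgm1 (1.07, adjusted p = 0.493), the chemokine gene Cxcl9 (1.30, adjusted p = 0.511) and Ifit2 (0.56, adjusted p = 0.718) were higher. Gbp2 differed by 0.27, Irgm1 by 0.59 and Cxcl9 by 0.64 without P59 replicate 1. Of the interferon genes 0 passed adjusted over the list alone, as over all genes tested by limma, with 4 at an unadjusted p under 0.05. Without P59 replicate 1 the median of the list was 0.0009, with an adjusted p of 0.434 and the test in the other direction, and without P54 replicate 1 the adjusted p was 0.0506. The list of barrier stress genes had a median of 0.15 (adjusted p = 0.0274; adjusted p = 0.600 with an estimated correlation), with 6 of 9 members higher. Of them 3 passed adjusted over the list alone, and S100a8 over all genes tested. Of the 3 lower members none had an unadjusted limma p under 0.05. Krt6b, 1 of these 3, named after its values were seen and not followed through the alternatives, differed by -1.25. S100a9, the partner subunit of S100a8, was higher by 1.71 (adjusted p = 0.290; 1.02 without P59 replicate 2) and the cornified envelope gene Sprr1a by 0.92 (adjusted p = 0.460). Without P54 replicate 1 the test of this list turned to lower (adjusted p = 0.941) though its median was 0.31, and without P59 replicate 1 the median was 0.08 (adjusted p = 0.465). The call was also lost without the intensity filter (adjusted p = 0.351) and after repeated quantile normalization (0.0972). Matrix proteases and their inhibitors had a median of 0.17 with 10 of 13 members higher (adjusted p = 0.0431; adjusted p = 0.700 with an estimated correlation), among them Adamts5 (1.12, adjusted p = 0.282) and Mmp3 (0.72, adjusted p = 0.656; 0.36 without P59 replicate 2). Of the protease genes 1 passed adjusted over the list alone, and 0 over all genes tested. This call was lost without P54 replicate 1 (adjusted p = 0.157), P59 replicate 1 (0.172) or P59 replicate 2 (0.0789), with the mean of all probe sets (0.132) and after repeated quantile normalization (0.0618).

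Genes of dermal white adipocytes were lower at P59, with 16 of 20 members down, a median of -0.30 and an adjusted p of 2.36e-05 with the preset correlation. It was not past the threshold (adjusted p = 0.600) with an estimated correlation. Among them 1 passed adjusted over the list alone, and 0 over all genes tested. Nnat, which encodes neuronatin, was lower by 1.41 on the log2 scale in a pair of separate groups (9.26 and 8.99 against 7.80 and 7.64, adjusted p = 0.106). The difference was -1.35 for the hormone-sensitive lipase gene Lipe (adjusted p = 0.511), -0.94 for Gpd1 (adjusted p = 0.764) and -0.80 for the lipid droplet gene Cidec (adjusted p = 0.599), each lowest in P59 replicate 2 and at -0.62, -0.15 and -0.42 without it. With the mean of their probe sets Lipe differed by -0.61 and Gpd1 by -0.59. Of the 16 lists called, the adipocyte and macrophage lists were those whose call with the preset correlation held whichever of the 4 arrays was left out. The macrophage call held only narrowly without P59 replicate 1. Cholesterol synthesis genes had a median of -0.13 with 16 of 20 members lower (adjusted p = 0.0177; adjusted p = 0.600 with an estimated correlation). Their regulator Srebf2 differed by -0.85 (adjusted p = 0.648), or -0.32 without P59 replicate 2, and Fdps by -0.34 (adjusted p = 0.893). Of the cholesterol genes 0 passed adjusted over the list alone, as over all genes tested by limma, with 1 at an unadjusted p under 0.05. The cholesterol list's call was lost without P54 replicate 2 (adjusted p = 0.443), P59 replicate 1 (0.0811) or P59 replicate 2 (0.0530).

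The bulge list, markers of follicle stem cells, had a median of -0.19 with 13 of 18 members lower (adjusted p = 0.000790; adjusted p = 0.600 with an estimated correlation). Fgf18, a growth factor made by bulge cells that holds follicles at rest, was at 7.40 and 7.65 at P54 and at 6.77 and 6.82 at P59 (difference -0.72, SE 0.23, adjusted p = 0.518). Differences were -0.76 for Foxp1 (adjusted p = 0.545), -1.39 for Ccn2 (adjusted p = 0.588), -0.72 for the stem cell marker Lgr5 (adjusted p = 0.628) and -0.61 for Col17a1 (adjusted p = 0.639). Ccn2 was at 11.88 and 12.02 at P54 and at 9.62 and 11.50 at P59, and differed by -0.45 without P59 replicate 1, while Lgr5 differed by -0.44 without P59 replicate 2 and by -0.39 with the mean of its probe sets. Cd34, another bulge marker, differed by -0.07 (95% interval -0.59 to 0.46). Adjusted over the list alone 0 bulge genes passed, as over all genes tested by limma, with 6 at an unadjusted p under 0.05. Without P59 replicate 1 the bulge median was -0.11 (adjusted p = 0.0811). Basal epidermal genes, 3 of which (Col17a1, Itga6 and Krt15) stand on the bulge list too, had a median of -0.24 with 10 of 12 lower (adjusted p = 0.00123; adjusted p = 0.600 with an estimated correlation). The hemidesmosome integrin gene Itgb4 differed by -0.87 (adjusted p = 0.650), Lamb3 by -0.56 (adjusted p = 0.744) and the basal keratin gene Krt5 by -0.45 (adjusted p = 0.840). Without P59 replicate 2 the differences of Itgb4 and Krt5 were -0.34 and -0.29. Of the basal genes 0 passed adjusted over the list alone, as over all genes tested by limma, with 3 at an unadjusted p under 0.05. The basal list's call was lost without P54 replicate 2 (adjusted p = 0.0704) or P59 replicate 1 (0.0770).

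Suprabasal and cornified epidermis genes had a median of -0.30 with 28 of 35 members lower (adjusted p = 0.000383; adjusted p = 0.700 with an estimated correlation), yet the members with the smallest p were higher. These were Rptn, a cornified envelope gene (1.57, adjusted p = 0.282), and the transglutaminase gene Tgm3 (0.66, adjusted p = 0.583), whereas Tgm1 differed by -0.85 (adjusted p = 0.698) and the corneodesmosin gene Cdsn by -0.46 (adjusted p = 0.801). Tgm1 was lowest in P59 replicate 2 and differed by -0.28 without it, when Rptn differed by 0.96. Of the suprabasal genes 1 passed adjusted over the list alone, and 0 over all genes tested. The median was -0.07 without P59 replicate 1 (adjusted p = 0.324) and -0.19 without P54 replicate 2 (adjusted p = 0.386). Notch signalling genes had a median of -0.17 with 10 of 12 lower (adjusted p = 0.0335; adjusted p = 0.600 with an estimated correlation), including the receptor genes Notch1 (-0.84, adjusted p = 0.478) and Notch3 (-0.51, adjusted p = 0.760; -0.91 with the mean of its probe sets). Adjusted over the list alone 0 Notch genes passed, as over all genes tested by limma, with 2 at an unadjusted p under 0.05. The Notch call was lost without P54 replicate 2 (adjusted p = 0.334) or P59 replicate 1 (median -0.07, adjusted p = 0.240).

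Circadian clock and output genes had a median of -0.15 with 13 of 20 members lower (adjusted p = 0.00196; adjusted p = 0.700 with an estimated correlation). Of the clock genes 4 passed adjusted over the list alone, and 0 over all genes tested. Per1, a core clock repressor, was at 10.63 and 10.23 at P54 and at 9.05 and 8.81 at P59, 2.83-fold lower (SE 0.24 on the log2 scale, adjusted p = 0.106). Wee1, a mitotic kinase gene under clock control, differed by -1.48 (adjusted p = 0.179), Dbp, a clock output transcription factor, by -0.79 (adjusted p = 0.490) and Ciart by -0.73 (adjusted p = 0.498). Arntl, whose transcript peaks opposite to Per1, was higher by 0.46 (adjusted p = 0.870), Per2 differed by -0.34 (adjusted p = 0.952) and Nr1d1 by -0.19 (adjusted p = 0.969). The other 2 probe sets of Per2 differed by -0.74 and -1.23. Arntl differed by 0.16 without P59 replicate 2 and by 0.24 with the mean of its probe sets. Without P59 replicate 1 the median of the list was 0.04 (adjusted p = 0.296), and Per2 was higher at P59 by 0.28.

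Immediate early genes, which respond within minutes to handling and tissue removal, had a median of -0.42 with 18 of 25 members lower (adjusted p = 4.84e-06; adjusted p = 0.700 with an estimated correlation). P54 replicate 1 stood apart from the other arrays: Nr4a1 was at 11.37 there and at 9.43, 9.44 and 8.56 in P54 replicate 2 and P59 replicates 1 and 2. Junb differed by -1.01 (adjusted p = 0.575), Dusp1 by -0.85 (adjusted p = 0.618) and Klf2 by -0.78 (adjusted p = 0.618). Junb was lowest in P59 replicate 2 and differed by -0.46 without it, whereas Dusp1 and Klf2 differed by -0.50 and -0.40 without P54 replicate 1. Of the immediate early genes 0 passed adjusted over the list alone, as over all genes tested by limma, with 6 at an unadjusted p under 0.05. Without P54 replicate 1 the median of the list was -0.009 (adjusted p = 0.115). Heat shock genes had a median of -0.21 with 15 of 19 members lower (adjusted p = 0.00813; adjusted p = 0.700 with an estimated correlation). They include the co-chaperone gene Dnajb1 (-0.77, adjusted p = 0.511) and Hspb8 (-0.43, adjusted p = 0.863), while the lens and muscle chaperone gene Cryab was higher by 0.41 (adjusted p = 0.870; 0.26 without P54 replicate 2). The other 2 probe sets of Hspb8 differed by -1.59 and 0.02. Adjusted over the list alone 0 heat shock genes passed, as over all genes tested by limma, with 1 at an unadjusted p under 0.05. Their median was -0.03 without P54 replicate 1 (adjusted p = 0.490) and -0.14 without P59 replicate 1 (adjusted p = 0.0811).

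**Figure D3:**
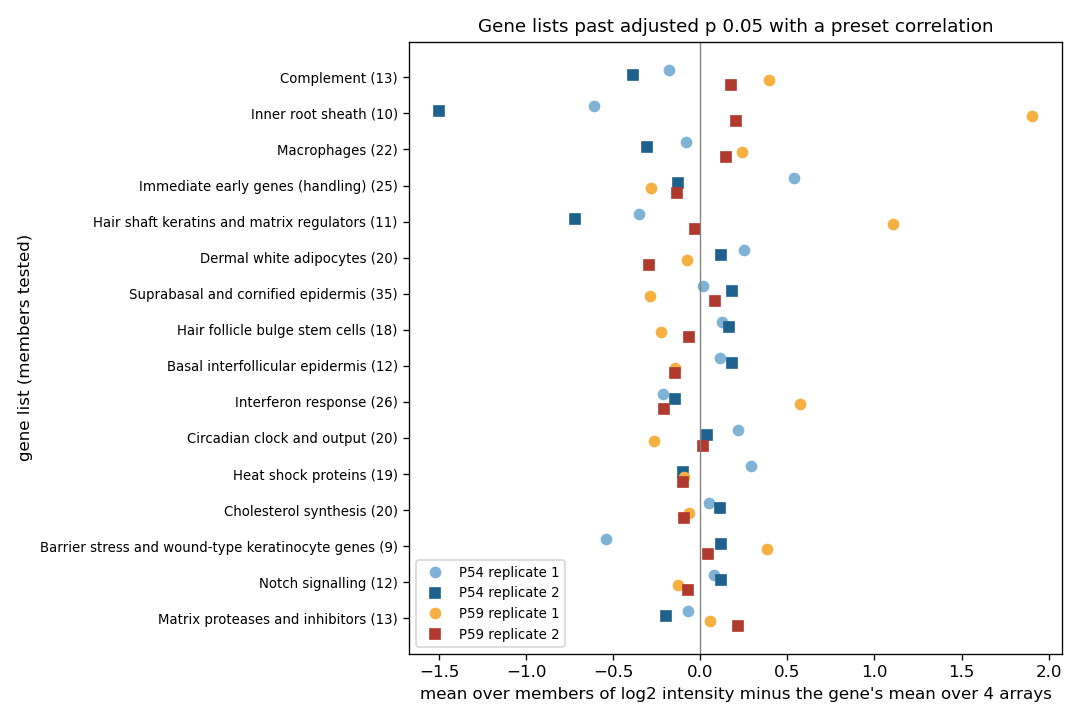
Mean over the tested members of a list of log2 intensity minus the gene's mean over the 4 arrays (horizontal axis), for the 16 lists past the adjusted threshold with the preset correlation (vertical axis, members tested in parentheses), with 1 point per array. P59 replicate 1 lies apart from the other arrays in inner root sheath (1.91), hair shaft (1.11) and interferon response (0.57), and P54 replicate 1 in immediate early genes (0.54) and heat shock proteins (0.29).

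Altogether 16 of the 47 lists tested passed with the preset correlation, 7 higher and 9 lower. With an estimated correlation 0 lists passed (lowest adjusted p = 0.600, with 0 at an unadjusted p under 0.05), and by fry 0 passed (lowest adjusted p = 0.508, with 3 at an unadjusted p under 0.05). The estimated correlation was below the preset 0.01 for the basal epidermal (-0.019), cholesterol (0.00013), barrier stress (-0.063) and Notch (-0.039) lists. Even so the unadjusted camera p of the basal list went from 0.000261 to 0.0614, and that of the cholesterol list from 0.00490 to 0.0920. Failing this test with 4 arrays is thus no measure of correlation within the lists. For the other called lists the estimate was above 0.01, from 0.020 (bulge) to 0.625 (interferon response), with 0.213 for complement and 0.156 for macrophages. Their p-values with the preset correlation therefore assume less correlation than was estimated. Of the 31 lists not past the threshold the lowest adjusted p was 0.0657, for Langerhans and dendritic cells, which passed without the filter (0.0217), with the mean of all probe sets (0.0148) and without P54 replicate 1 (0.0138). Fatty acid and triglyceride synthesis genes followed (median -0.10, 11 of 18 members lower, adjusted p = 0.0705). They passed without the filter (adjusted p = 0.0236), with the mean of all probe sets (0.0292), after repeated quantile normalization (0.0449) and without P54 replicate 1 (0.00905). Fibrillar collagen and matrix genes had a median of 0.13 (adjusted p = 0.0717), with Thbs2 (1.20, adjusted p = 0.272) and the crosslinking enzyme gene Lox (1.02, adjusted p = 0.478; 0.59 without P59 replicate 2) higher. That list passed without the filter (adjusted p = 0.0406) and with the 60th percentile filter (0.0309). It did not pass when any 1 array was left out, and its median was 0.04 without P54 replicate 2 (adjusted p = 0.133). Skeletal muscle genes had a median of 0.13 (adjusted p = 0.130), which was 0.39 and past the threshold without P54 replicate 1 (adjusted p = 0.000279) or P59 replicate 2 (1.13e-09), and -0.12 and -0.10 without P54 replicate 2 and P59 replicate 1. Pigment cell genes had a median of 0.15 (adjusted p = 0.303), which was 0.43 without P59 replicate 1 and 0.35 without P59 replicate 2. Neutrophil, B cell and red cell lists had fewer than 5 tested members and were not tested as lists.

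The regulators of telogen fixed for naming showed differences in both directions, none past the adjusted threshold. Bmp2 and Bmp4, ligands that keep follicles refractory in early telogen, differed by 0.18 (95% interval -0.43 to 0.79) and 0.08 (-0.45 to 0.61), and without P59 replicate 2 by -0.15 and -0.07. Their target Id1 differed by -1.08 (SE 0.37, adjusted p = 0.588), with 9.60 and 9.73 at P54 and 9.25 and 7.93 at P59, and by -0.42 without P59 replicate 2. Fgf7, a dermal papilla growth factor, was higher by 0.78 (95% interval 0.21 to 1.35, adjusted p = 0.559; 0.51 without P59 replicate 2), and the secreted Wnt antagonist gene Sfrp4 by 0.67 (0.15 to 1.20, adjusted p = 0.599). Of Wnt targets, Lef1 was higher by 0.38 (-0.12 to 0.88) and Axin2 by 0.05 (-0.48 to 0.57), the latter turning to -0.53 with the mean of its probe sets. The proliferation marker Mki67 differed by 0.11 (-0.39 to 0.60). Fgf10, Dkk1, Wnt10b, Shh and Gli1 lay below the intensity filter and were not tested. Shh was at 5.85 and 6.14 at P54 and at 6.98 and 6.20 at P59.

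The lists around these regulators did not pass in the chosen setting: BMP signalling had an adjusted p of 0.630, secreted Wnt inhibitors 0.830, hedgehog signalling 0.871, FGF signalling 0.377, dermal papilla 0.558, secondary hair germ 0.285 and cell cycle genes 0.545. Wnt ligands and feedback targets had a median of -6.2e-05, with 9 of 18 members higher and 9 lower, and an adjusted p of 0.0939. The epithelial ligand genes Wnt7b (-1.38, adjusted p = 0.359) and Wnt10a (-0.63, adjusted p = 0.604) were lower. Wnt7b differed by -0.79 without P59 replicate 2. The Wnt list passed, as lower, with the 60th percentile filter (median -0.20, adjusted p = 0.00560) and with the mean of all probe sets (median -0.22, adjusted p = 0.00564), and the cell cycle list with the 60th percentile filter (median -0.18, adjusted p = 0.0204). The median had the opposite sign to the test in the BMP list (0.06, tested lower), in the cell cycle list (0.03, tested lower) and in the Wnt inhibitor list (-0.02, tested higher), as in the TGF-beta and ribosomal protein lists.

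P59 replicate 2 differed from the other arrays in the 3' to 5' gap of the Gapdh and Actb control transcripts. The gap of Gapdh was 4.57 (log2) there against 0.34, 0.20 and 0.23 on the other arrays, and that of Actb 1.64 against 0.45, 0.52 and 0.18. The 5' set of Gapdh was at 8.62 there and between 13.19 and 13.69 on the other arrays. The 3' and 5' sets of the transferrin receptor transcript lay below the intensity filter on all 4 arrays, as did the 5' set of Pcx on all but P54 replicate 2, so the gaps of these 2 transcripts are not read. The mean gap over all 4 transcripts was 2.69 against 1.47, 1.26 and 1.41. In P59 replicate 2 alone, 206 genes lay at least 1 (log2) below each of the other 3 arrays, compared with 1, 28 and 12 genes in P54 replicate 1, P54 replicate 2 and P59 replicate 1. Of the 10 genes with the largest negative differences 4 were among those 206, and of the 10 with the largest positive differences 0. The members of lists named above that were among the 206 are Lipe, Gpd1, Srebf2, Itgb4, Tgm1, Junb, Id1, Wnt7b and C1qa. Tmem120a was at 8.20, 8.20 and 7.79 on the other arrays and at 4.54 in P59 replicate 2 (difference -2.04, adjusted p = 0.618), and the laminin-binding adhesion gene Bcam was at 9.46, 10.07 and 8.97 against 6.57 (-2.00, adjusted p = 0.490). The histone demethylase gene Kdm6b differed by -1.90 (adjusted p = 0.490) and the scaffold gene Iqgap1 by -1.71 (adjusted p = 0.400). Without P59 replicate 2 these 4 genes differed by -0.42, -0.80, -0.96 and -0.87. With the mean of all probe sets Kdm6b differed by -0.80 and Iqgap1 by -0.48, their other sets differing by less. Crim1 (-1.91), Rbfox2 (-1.78), Il6ra (-1.74), Errfi1 (-1.71), Il31ra (-1.70) and Gdap10 (-1.69) complete the 10, with adjusted p between 0.290 and 0.618. All but Errfi1 were highest in P54 replicate 2, and without it Crim1 differed by -0.91, Rbfox2 by -0.97, Il6ra by -0.39, Il31ra by -0.97 and Gdap10 by -1.01. Errfi1, at 12.21 and 11.73 at P54 and 9.49 and 11.03 at P59, differed by -0.95 without P59 replicate 1, and Gdap10 by -1.07. With the mean of all probe sets Crim1 differed by -0.93, Rbfox2 by -0.52 and Il6ra by -1.11. Without P59 replicate 2, 112 of the 276 lower genes and 188 of the 331 higher genes at the unadjusted p and fold limits were still counted.

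**Figure D4:**
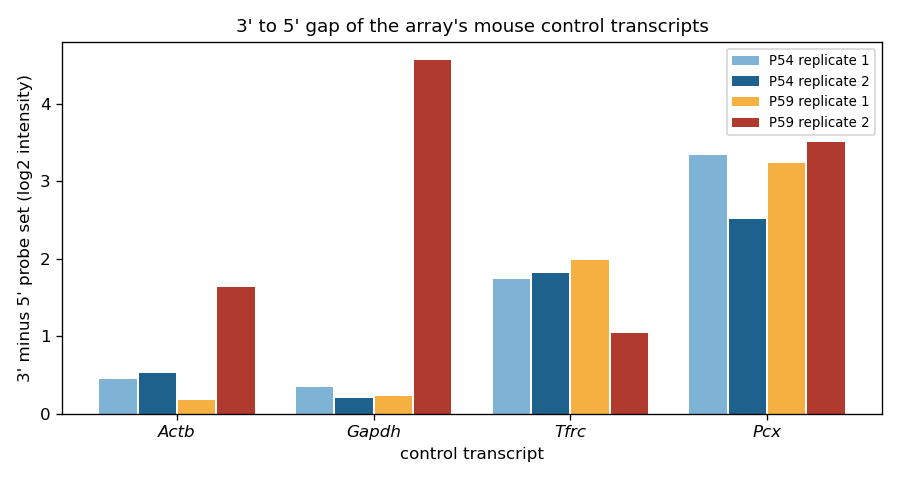
Log2 intensity of the 3' minus the 5' probe set (vertical axis) of 4 mouse control transcripts (horizontal axis), with 1 bar per array. P59 replicate 2 has the widest gap for Gapdh (4.57) and Actb (1.64), while the gaps of Tfrc and Pcx rest on 5' sets that lie below the intensity filter on most arrays.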

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

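All alternatives here were planned. The 2 genes past the adjusted threshold in the chosen setting became 0 in 5 settings: without the filter (1122 genes at an unadjusted p under 0.05 in limma), with the 60th percentile filter (457; both genes fall below it), with the mean of all probe sets (705; Akr1cl falls below the filter), with every probe set (1501) and after repeated quantile normalization (759). The count was 24 with the trend and robust prior (18 higher, 6 lower), 49 after median centring (37 higher and 12 lower, against 2 and 0) and 9 with array weights, S100a8 and Akr1cl among them each time, and between 29 and 402 without 1 array. The 607 genes at 1.5-fold and unadjusted p became 381 with the 60th percentile filter and 1396 with every probe set, where fewer and more features were tested, and 273 to 1707 without 1 array. Lists past the threshold went from 16 to 0 with an estimated correlation and to 0 with fry, and to between 3 and 20 without 1 array, 3 being the count without P59 replicate 1. Fits without 1 array leave 1 residual degree of freedom and assume that the lone sample of a group varies like the other group. In the fit with the replicate number as a block, 156 genes passed (75 higher, 81 lower) and 14 lists, the cholesterol, Notch and protease lists being lost and the fatty acid and triglyceride synthesis list gained (adjusted p = 0.0490). With that block, as without either P54 array, the estimated prior was 1 spread for all genes, so these counts are counts of large differences. The numbers are not shown to pair the arrays: the correlation of same-numbered deviations was -0.037 over 2 pairs. Array weights were tied within each group, at 1.52 for both P54 arrays and 0.66 for both P59 arrays. That setting therefore could not weight down P59 replicate 2 alone.

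Some results changed direction (for lists, that of the test), and the cause was not tested; of these the interferon and barrier stress lists were past the threshold in the chosen setting, with the preset correlation. With the mean of all probe sets Ryr1 was -0.36, Axin2 -0.53, the Wnt inhibitor list -0.078 and the hedgehog list 0.0015. Without the filter the Wnt inhibitor list was -0.038 and the hedgehog list -0.0025, and with the 60th percentile filter the FGF list was 0.0035. The other changes of direction came without 1 array, and are given as the lowest and highest of the 4 such values. For clock genes and telogen regulators the range was -0.96 to 0.28 for Per2, -0.67 to 0.28 for Nr1d1, -0.15 to 0.52 for Bmp2, -0.070 to 0.23 for Bmp4, -0.13 to 0.23 for Axin2 and -0.24 to 0.10 for Cd34. For members of lists it was -0.047 to 1.33 for Stfa3, -0.72 to 0.0092 for Bmp6, -0.42 to 0.025 for Gli2, -0.17 to 0.57 for Gas1, -2.83 to 0.48 for C1qa, -0.22 to 0.78 for C1qb and -0.021 to 0.49 for C1qc. List medians ranged from 0.00095 to 0.58 for interferon response, 0.080 to 0.60 for barrier stress (0.31 without P54 replicate 1, where its test turned), -0.075 to 0.16 for BMP, -0.13 to 0.14 for Wnt inhibitors, -0.13 to 0.11 for hedgehog, -0.026 to 0.035 for cell cycle and -0.12 to 0.39 for muscle. Of lists given by their adjusted p alone, secondary hair germ turned to 0.13 without P59 replicate 2. The other named genes, each followed through its chosen probe set where every set was tested, and the other lists with a median or named members kept their direction in each alternative run on them. Of 58 named genes with another set tested there, 10 had one of opposite sign (Axin2, Cdon, Crim1, Eln, Gas1, Hspb8, Iqgap1, Kit, Myl4 and Ryr1).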

Other observations

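The tests on follicle order, cell cycle genes, opposite-phase clock genes, P54 replicate 1 and the other splits of the arrays were chosen only after the results they measure were seen. Those on control transcripts and on other probe sets were written before their outcomes, but for a pattern that already named P59 replicate 2. Beyond the lists described, the following single genes had separate groups, all chosen after their values were seen except Mb, Crabp1, Mlana and Ednrb, and none was past the adjusted threshold. They were tested for no shared theme, and the fixed collagen and muscle lists did not pass in the chosen setting (adjusted p = 0.0717 and 0.130), though each passed in 2 of the alternatives. Higher at P59 were C1qtnf3 (1.75, adjusted p = 0.0934), the oxidase gene Nox4 (2.15, adjusted p = 0.0939), the matricellular gene Ccn5 (1.41, adjusted p = 0.106), the lubricin gene Prg4 (1.61, adjusted p = 0.179), Itgbl1 (1.30, adjusted p = 0.179) and the osteomodulin gene Omd (1.51, adjusted p = 0.282). Inmt, a methyltransferase gene, was higher by 1.79 (adjusted p = 0.141). Others higher were Lrrc2 (1.55, adjusted p = 0.179), Lmod2 (1.61, adjusted p = 0.290) and Myl4 (1.38, adjusted p = 0.497), and the myoglobin gene Mb (1.22, adjusted p = 0.460). Crabp1, a marker of papilla and other dermal cells, was lower at P59 (-1.12, adjusted p = 0.448), and the melanocyte genes Mlana (1.19, adjusted p = 0.515) and Ednrb (0.71, adjusted p = 0.518) were higher. Without P59 replicate 2 the differences were 0.53 for Mlana, -0.65 for Crabp1 and 0.96 for Omd, without P54 replicate 2 they were 0.66 for Mb and 1.02 for Lmod2, and without P59 replicate 1 that of Myl4 was 0.62. With the mean of their probe sets Mb differed by 0.62 and Myl4 by 0.66.

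Transcripts low in P59 replicate 2 alone may reflect RNA that was shorter or more degraded in that sample. The mean 3' to 5' gap of its control transcripts exceeded the highest of the other arrays by 1.223 (log2), mainly through Gapdh and Actb; the transferrin receptor sets, below the intensity filter, speak neither for nor against it. If signal was lost in some probe sets and not in others of the same gene, the other sets should fall less: over 55 of the 206 genes, 68 other probe sets fell by 0.414 of the first sets' fall (0.231 to 0.635), an interval that spans 0.5, and the first sets were chosen for their fall, so this stays open. A biological difference of that mouse skin was not tested and also stays open.

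The follicle keratin genes may come from one source of hair follicle transcript present in varying amount per array. Of the 21 tested members of the inner root sheath and hair shaft lists, 11 ranked the arrays in the same order (P59 replicate 1, P59 replicate 2, P54 replicate 1, P54 replicate 2), an order picked as the commonest. Of the 14 members with both P59 arrays above both P54 arrays, which leaves 4 orders, these 11 make up 78.6%, against 20.2% of the other 2046 tested genes with the P59 arrays above. Growing follicles hold dividing matrix cells, but the cell cycle list was only 0.051 higher in the array with the most keratin signal than in the one with the least (SD over 28 members 0.305), while the keratin lists differed by 2.58. At P59 16 members of the cell cycle list were higher and 12 lower. At an unadjusted limma p under 0.05, Nusap1 (0.60), Bub1b (0.53) and Ccnb2 (0.50) were higher and Mcm5 (-0.74) was lower. Each had separate groups, and none was past the adjusted threshold. With the mean of its probe sets Bub1b differed by 0.34. The list's mean of 7.91 in the array with the least leaves room for a small share of dividing cells to go unseen, so whether P59 skin held a few follicles that had entered growth, or a piece of skin with remnants of the former cycle, cannot be told apart. The age of the mice, which the design names, remains open as well.

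Per1, Wee1, Dbp and Ciart lower at P59 could follow from a different hour of sampling on the 2 days. The genes of opposite phase (Arntl, Clock, Nfil3 and Cry1) had a median of 0.17, the direction that explanation needs, but only Arntl had separate groups, and its difference was 0.16 without P59 replicate 2, so hour and age cannot be told apart. A handling response limited to P54 replicate 1, where immediate early genes were highest, would leave little difference in the 4 genes without that array. Their median difference without it was -1.103. The 4 genes were named for the smallest p and had separate groups, so a fall without that array was nearly fixed in advance. Over the 20 tested clock genes the median was -0.11 without P54 replicate 1, against -0.15 with all arrays (SD over members 0.53). Most of the list's small difference remained without that array. It lies well within the spread of the members, so for the list this stays open.

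The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 2 genes past the adjusted threshold and the highest of the others 0, so 1 of the 3 splits gave as many, and it gave 16 lists where the highest of the others, P54 replicate 1 with P59 replicate 2 against the rest, gave 14, again 1 of 3.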
